A study of Mus musculus with 15 samples.

How the data were processed

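Messenger RNA was measured by strand-specific RNA sequencing (TruSeq Stranded mRNA libraries) in mouse brain, in 15 libraries from 5 groups of 3. The deposited values are whole-number read counts per gene symbol, 1 file per library, and all files list 45777 symbols in one order. Per the submitters' processing notes, bcl2fastq 2.20.0, Trimmomatic, HISAT2 2.1.0 and StringTie 2.1.3b were used with the GRCm38/mm10 mouse genome. The annotation, the strand setting and the way reads shared by several genes were counted are not given in the sources used here. Overlapping genes, antisense genes and near-identical gene copies are therefore uncertain. The files of the 6 libraries from inhibitor-treated mice differ from the other 9 in the number of empty trailing columns only, so their handling may have differed and would then follow the treatment.

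Groups and replicate numbers were taken from the sample labels. The labels do not say outright that each library is a separate mouse, so p-values measure only the spread between these samples, which may be technical. Total counts ran from 58149722 to 68257095 reads per library, and 3 reads in a library of this size correspond to at most 0.0516 CPM, the read count scaled to the library total. No library pair within a group agreed within sampling noise, as the chi-square per degree of freedom ran from 31.7 to 512, so no library was counted as a duplicate.

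Genes were tested with edgeR 4.0.16 (R 4.3.3) on the deposited counts, with TMM normalization, filterByExpr by group, 1 quasi-likelihood fit of all 15 libraries without covariates, and Benjamini-Hochberg adjustment at 0.05. This left 21821 genes. Standard errors of log2 fold changes were the fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM, as mean ± SD over 3 libraries. The 42 gene lists were fixed before the data were examined, as were the design, the alternatives and the rule for named genes, and 701 of 716 list entries matched a symbol. Of these lists, 41 were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and at least 5 measured genes. The remaining list was not set-tested. An estimated correlation and fry were the alternatives.

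Named genes in each main comparison were the 10 with the largest rise and the 10 with the largest fall among genes passing the adjusted threshold, with a mean of at least 1 CPM and no overlap between the 3 libraries of either group, leaving out predicted genes and mitochondrial tRNAs. To these were added study genes (Nr4a2, Btk, Th, Slc6a3, Ddc and Slc18a2) and up to 4 members with the smallest p of each called list and of the homeostatic microglia, dopamine neuron and inflammation lists. A selection of these is printed, and results for some genes are not reported here. Regional markers and the genes of the chromosome 4 and 14 clusters were chosen after their values were seen where the text says so. Coordinates come from the RefSeq table of GRCm38.p6, in which 40686 symbols were found.

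Replicate numbers met the rule for pairing (every pair of equal number correlated above 0.1) only between the levodopa and control groups, where deviations from the group means correlated at 0.286, 0.801 and 0.368. Pairs of unequal number reached 0.533 (levodopa 1 with control 3) and 0.599 (levodopa 3 with control 1), so libraries 1 and 3 were not closest to their own number. The labels do not state what the number stands for. The fit with the replicate number as a block called 0 genes there, as did the fit without it.

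The tests were checked on counts simulated from the real means and library sizes. Each gene was drawn on its own, with no regional differences between libraries. The recovered and false calls below therefore do not give the rates where libraries differ in regional tissue. With 200 genes changed in the low-dose against MPTP comparison (21434 genes tested), 39 of 100 genes changed by 2-fold and 92 of 100 changed by 4-fold were recovered, with 11 false calls. In the simulated MPTP against control comparison (21394 genes tested), 31 of 100 and 76 of 100 were recovered, with 3 false calls. Alternatives were RLE and upper-quartile normalization, DESeq2 1.42.0, no filter, a filter of 5 CPM in 3 libraries, fits of only the compared groups, the replicate block, and each library left out in turn. After seeing the data 2 more were added. One left out the 2 libraries with high cerebellar markers. The other used 3 regional list scores as covariates, those of the cerebellum, the cortex and hippocampus, and the thalamus and midbrain lists. The planned test on TPM values was not run, since the files hold counts only.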

Results

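The series measured brain gene expression in mice given MPTP, a toxin that damages dopamine neurons, and then levodopa or an inhibitor of BTK, the Bruton tyrosine kinase of B cells and microglia. Its title names Nurr1, the transcription factor encoded by Nr4a2. Controls on a normal diet, MPTP alone, MPTP followed by levodopa, and MPTP followed by a low or a high dose of the inhibitor had 3 libraries each, while the protocol gives 8 mice per group. MPTP was given at 20 mg/kg/day for 1 week and the drugs for 4 weeks. The labels give the inhibitor doses both as 1 and 2 µg/kg/day and as 25 and 50 pM, and the levodopa route both as oral and as intraperitoneal. The tissue is labelled brain, with no region. Total counts ran from 58149722 to 61998459 reads in the 6 inhibitor libraries and from 63314658 to 68257095 in the other 9.

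The libraries differed in markers of brain regions, including within groups. Gabra6, a GABA receptor subunit of cerebellar granule cells (chromosome 11, 42306437 to 42321072 of GRCm38), reached 649 CPM in control 2 and 556 CPM in levodopa 2, against at most 3.18 CPM in the other 13. In these same libraries the dopamine transporter gene Slc6a3 had 0 and 0.129 CPM. Drd1, a striatal dopamine receptor, had 89.5 CPM in control 1 and 8.20 CPM in control 3. Neurod6, a transcription factor of cortical and hippocampal neurons, ranged from 20.0 to 93.3 CPM in the 6 inhibitor libraries and from 0.98 to 7.03 CPM in the other 9. Gabra6 and Drd1 were chosen after their values were seen. The mitochondrial ribosomal RNAs took 0.937% to 1.48% of the reads in the inhibitor libraries and 0.244% to 0.88% in the others.

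**Figure D1:**
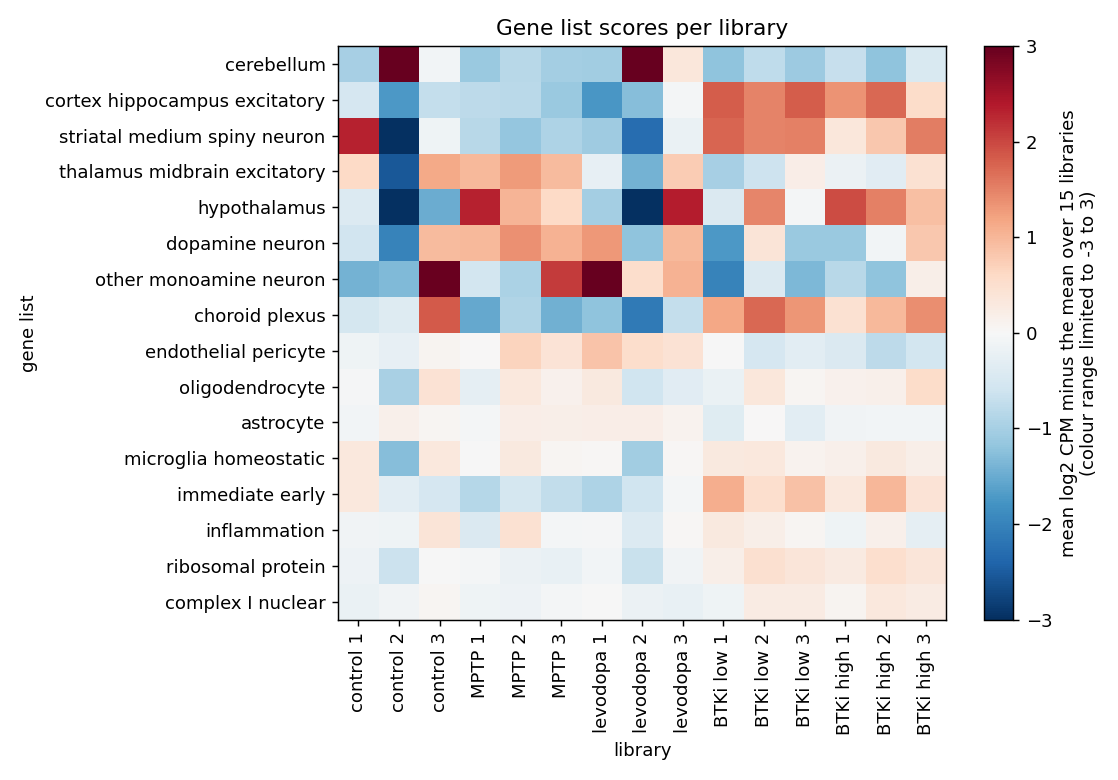
Scores of 16 gene lists (vertical axis) in the 15 libraries (horizontal axis), as the mean log2 CPM of the members minus its mean over all libraries, with the colour range limited to 3 either way. The cerebellum list stands at 5.23 in control 2 and 4.97 in levodopa 2, and the cortex and hippocampus list is above 0 in all 6 inhibitor libraries and below 0 in the other 9.

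The first comparison asked what MPTP changed against control mice. Genes of dopamine synthesis and transport had higher mean levels after MPTP, with wide spread. Th, the rate-limiting enzyme of dopamine synthesis (chromosome 7, 142892779 to 142899995), had 52.1 ± 15.8 CPM after MPTP and 13.7 ± 12.3 CPM in controls (SD, n = 3 each), a log2 fold change of 1.92 (SE 0.96) with an edgeR adjusted p of 0.717. Slc6a3 had 84.5 ± 33.5 and 20.1 ± 30.6 CPM, and Nr4a2 had 19.4 ± 11 and 14.7 ± 11.8 CPM. Nr4a2 had 307, 1680 and 803 reads in controls 1, 2 and 3, and 1250, 2113 and 603 in MPTP 1, 2 and 3. The highest control was thus control 2, a library with high cerebellar markers. With each library left out in turn, the log2 fold change of Nr4a2 ran from -0.12 to 1.24. Among the controls, Th was 5.86, 7.42 and 27.9 CPM. With edgeR, 0 of 21821 genes passed, while 1445 had an unadjusted p under 0.05 and DESeq2 called 51.

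By lists, members of the endothelial and pericyte list were higher on balance after MPTP (median log2 fold change 0.49, camera adjusted p = 8.5e-08), with 0 of 18 members passing and 3 rising when adjusted over the list alone. Its members include the glucose transporter gene Slc2a1 (97.9 against 69.0 CPM) and the VEGF receptor gene Flt1 (72.8 against 37.0 CPM). The dopamine neuron list was also higher on balance (median 1.04, adjusted p = 0.00035), with 0 of 22 members passing over all genes and 0 adjusted over the list alone. Both calls ended with adjusted p = 0.751 with an estimated correlation. The dopamine neuron score was -0.58, -2.00 and 0.94 in controls 1, 2 and 3, and from 0.96 to 1.37 in the MPTP libraries. That list stayed called without control replicate 2 (adjusted p = 0.0017) but not with regional covariates (adjusted p = 0.0795). The hypothalamus list was higher (median 2.24, adjusted p = 0.751 with an estimated correlation), and its peptide gene Hcrt had 37.3 CPM after MPTP and 0.10 CPM in controls. Lower on balance were the choroid plexus list (median -1.98, 0 passing and 9 of 16 falling adjusted over the list alone), the striatal list (median -1.56, 5 of 17 falling adjusted over the list alone), the cerebellum list and the immediate early list, with adjusted p from 0.751 to 0.92 with an estimated correlation. The striatal score was 2.30 in control 1 against -3.13 and -0.13 in controls 2 and 3, and the choroid plexus score was 1.84 in control 3 against -0.54 and -0.39 in controls 1 and 2. Without control replicate 1, the log2 fold change of the striatal gene Adora2a went from -4.89 to -2.00. Ttr, the choroid plexus transport protein, had 3.59 ± 3.53 CPM after MPTP and 333 ± 455 CPM in controls. These 15 called lists became 0 with an estimated correlation, with adjusted p from 0.751 to 0.935 across them, and 9 without both libraries of high cerebellar markers. The homeostatic microglia list was higher by a median of 0.14 (adjusted p = 0.0217, and adjusted p = 0.926 with an estimated correlation), with Cx3cr1 at 41.0 and 33.4 CPM. Its score was -1.28 in control 2 and 0.309 and 0.305 in controls 1 and 3, and without control replicate 2 the list was lower after MPTP (adjusted p = 0.0212). The cerebellum and the thalamus and midbrain lists were no longer called without that library (adjusted p = 0.711 and 0.318), and the inflammation list did not pass (adjusted p = 0.90).

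**Figure D2:**
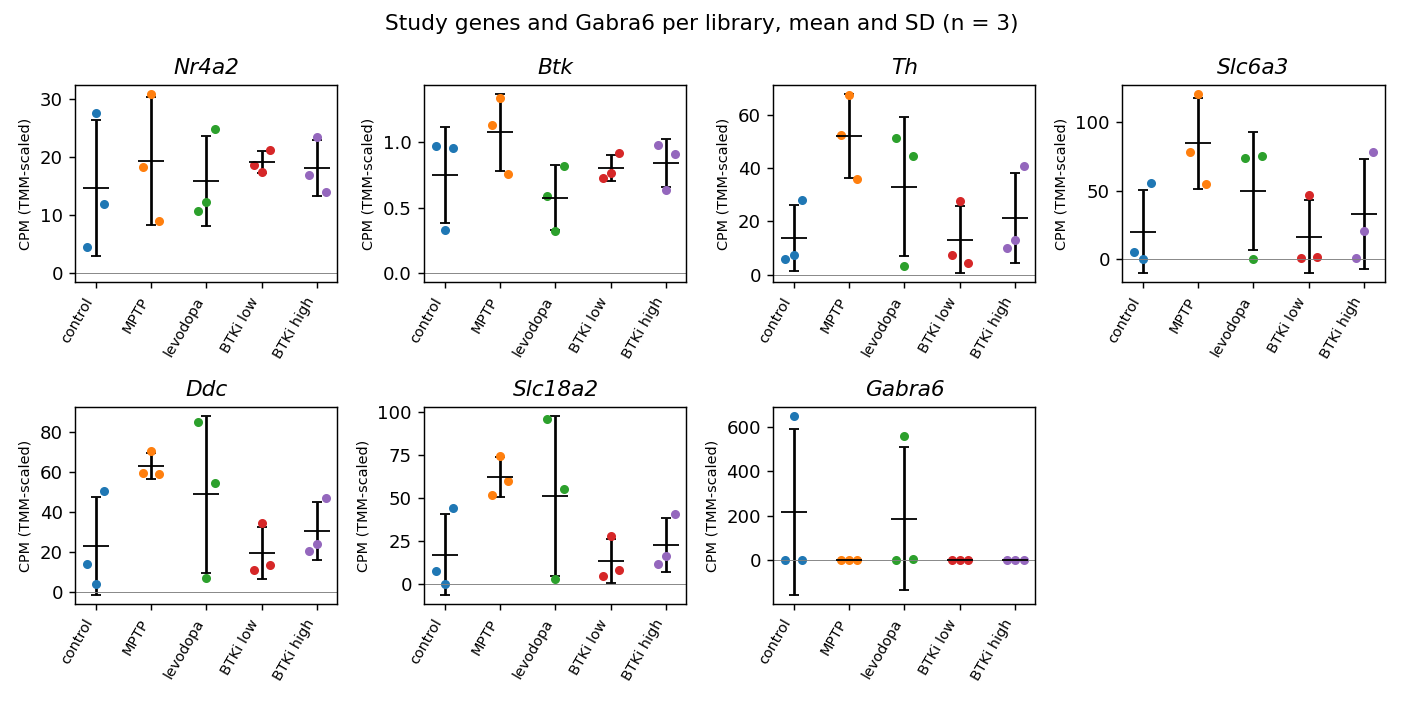
Levels in TMM-scaled CPM (vertical axes, linear) of 6 study genes and Gabra6 in each library (points), with the group mean and SD (horizontal and vertical bars, n = 3; some SD bars reach below 0), for 5 groups on the horizontal axes. Th means are 13.7 CPM in controls and 52.1 CPM after MPTP, and Gabra6 is high in 1 control and 1 levodopa library.

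Levodopa after MPTP was compared with MPTP alone. Dopamine genes had lower means that lay within the spread. Of these, Th, Slc6a3, Ddc and Slc18a2 were lowest in levodopa 2, the library with high cerebellar markers. Th was 51.5, 3.28 and 44.4 CPM in levodopa 1, 2 and 3, and without levodopa 2 the log2 fold changes of Ddc and Slc18a2 turned to 0.14 and 0.27 and that of Th went to -0.13. With all libraries, Th had 33.1 ± 26.0 against 52.1 ± 15.8 CPM (SD, n = 3 each), a log2 fold change of -0.66 (SE 0.93, edgeR adjusted p = 0.954), and Nr4a2 had 15.96 ± 7.76 against 19.4 ± 11 CPM, with a fold change of Nr4a2 that turned to 0.23 without MPTP replicate 2. The thalamus and midbrain list was lower on balance (median -0.88, camera adjusted p = 0.0017, and adjusted p = 0.86 with an estimated correlation), with Ntng1 at 61.7 against 143 CPM. With regional covariates the list was not called and its direction turned (adjusted p = 0.861). Its own score is among those covariates, so that loss was built into the fit. The homeostatic microglia list was lower (median -0.37, adjusted p = 0.00026), and the cerebellum list was higher (median 2.65, 0 of 16 passing and 4 rising adjusted over the list alone), both with adjusted p = 0.86 with an estimated correlation. Microglia scores were -1.05 in levodopa 2 and 0.025 and 0.036 in levodopa 1 and 3, and the thalamus and midbrain score was -1.43 in levodopa 2 and 0.77 in levodopa 3. Without levodopa replicate 2 the microglia and cerebellum lists were not called (adjusted p = 0.463 and 0.69), while the thalamus and midbrain list was (adjusted p = 0.0109). The endothelial and pericyte list and the leptomeninges list were higher (medians 0.15 and 0.42, both with adjusted p = 0.0065, and adjusted p = 0.86 with an estimated correlation), with 0 members passing. They stayed called without levodopa replicate 2 (adjusted p = 0.0042 and 8e-10), without both libraries of high cerebellar markers (adjusted p = 0.0106 and 4.1e-07) and with regional covariates (adjusted p = 0.004 and 0.0296). All of these fits kept MPTP 1, the MPTP library with the lowest scores on both lists. Endothelial scores were 0.00038, 0.67 and 0.42 in MPTP 1, 2 and 3, and leptomeninges scores were -0.96, 0.26 and 0.32. Levodopa 1, 2 and 3 had endothelial scores of 0.85, 0.54 and 0.43 and leptomeninges scores of 0.85, -0.38 and 0.50. On both lists these overlapped the scores of MPTP 2 and 3, so the higher levels with all libraries rest largely on MPTP 1. On the leptomeninges list, levodopa 1 and 3 still lay above MPTP 2 and 3. Each of the 14 called lists had adjusted p = 0.86 with an estimated correlation. The inflammation list did not pass (adjusted p = 0.753). With edgeR 0 genes passed, 645 had an unadjusted p under 0.05 and DESeq2 called 2, and 1 gene passed without levodopa replicate 3. Without both libraries of high cerebellar markers, 4 lists were called in place of 14, and 5, 8 and 9 were called without levodopa replicate 2, MPTP replicate 1 and MPTP replicate 2. Levodopa against controls also gave 0 genes, with 816 at an unadjusted p under 0.05, 66 by DESeq2 and 1 without levodopa replicate 3.

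The low dose of the inhibitor after MPTP was compared with MPTP alone, the comparison that asks what inhibition of BTK changes in the treated brain. Of the lists for cortex and hippocampus, striatum, choroid plexus and neuronal activity, 6 of 16, 4 of 17, 7 of 16 and 12 of 24 members rose, and of those for blood vessels, astrocytes and dopamine neurons 8 of 18, 3 of 14 and 2 of 22 fell. None of these list calls held with an estimated correlation (adjusted p from 0.387 to 0.507 with an estimated correlation). Neurod6 rose from 1.75 ± 0.70 to 78.1 ± 12.0 CPM (SD, n = 3 each; log2 fold change 5.47, SE 0.79, adjusted p = 0.0037, edgeR). In all, 1042 genes rose and 819 fell of 21821.

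Of the cortex and hippocampus list 6 of 16 members rose, 0 fell and 10 did not pass, and 12 rose adjusted over the list alone; Neurod6 rose by 5.47 and Emx1 by 5.12 on the log2 scale. Of the striatal list 4 of 17 rose (7 adjusted over the list alone), among them Ppp1r1b, a dopamine-regulated phosphatase inhibitor (24.2 to 319 CPM), the adenosine receptor gene Adora2a (1.47 to 57.2 CPM) and the enkephalin precursor Penk (51.8 to 367 CPM). In the untreated control 1, Ppp1r1b, Adora2a and Penk had 35583, 8053 and 34659 reads. The inhibitor libraries had at most 21041, 3977 and 25041. Of the choroid plexus list 7 of 16 rose (12 adjusted over the list alone), with Ttr from 3.59 to 1149 CPM and the potassium channel gene Kcne2 by 4.42 on the log2 scale. Ttr had 3049, 5812 and 57709 reads in controls 1, 2 and 3, and 15824 to 83977 in the inhibitor libraries. The immediate early list, genes switched on by neuronal activity, had 12 of 24 members rising (13 rising and 1 falling adjusted over the list alone). Arc rose from 20.0 to 163 CPM (log2 fold change 3.03, SE 0.50), Egr1 from 59.7 to 263 CPM and Nr4a3, a relative of Nr4a2, from 7.10 to 46.4 CPM. Adjusted p with an estimated correlation was 0.387 for the cortex and hippocampus and immediate early lists, 0.507 for the striatal list and 0.496 for the choroid plexus list. All 6 inhibitor libraries had a higher cortex and hippocampus score than the other 9, a measured difference that goes with each of these groups.

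Of the endothelial and pericyte list 8 of 18 fell and 0 rose (10 falling adjusted over the list alone), among them the drug efflux pump gene Abcb1a (41.3 to 13.7 CPM), the adhesion gene Pecam1 (20.0 to 8.85 CPM) and Flt1 (72.8 to 30.7 CPM), with adjusted p = 0.504 with an estimated correlation. Of the astrocyte list 3 of 14 fell (5 adjusted over the list alone), with the water channel gene Aqp4 from 282 to 125 CPM and the bicarbonate transporter gene Slc4a4 from 376 to 162 CPM. Of the dopamine neuron list 2 of 22 fell and 20 did not pass (2 adjusted over the list alone), namely Ret, a receptor of glial-derived neurotrophic factors (83.3 to 18.1 CPM), and the retinaldehyde dehydrogenase gene Aldh1a1 (209 to 66.3 CPM). Both lists had adjusted p = 0.504 with an estimated correlation. With regional covariates Ret and Aldh1a1 were not called, and their log2 fold changes turned to 0.15 and 0.20. Th had 13.2 ± 12.7 CPM (log2 fold change -1.98, SE 0.97, adjusted p = 0.219), Btk 0.80 ± 0.098 against 1.07 ± 0.291 CPM, and Nr4a2 19.2 ± 1.94 against 19.4 ± 11 CPM (log2 fold change -0.02, SE 0.56). Of the interferon list 2 of 20 fell (2 adjusted over the list alone), Oasl2 and Rsad2, with adjusted p = 0.507 with an estimated correlation. In the thalamus and midbrain list 0 of 12 passed, with a median of -1.55 (adjusted p = 0.504 with an estimated correlation). The 3 low-dose libraries, in which these lists were lower, had higher cortex and hippocampus scores than the 3 MPTP libraries.

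Some genes of protein synthesis, of complexes II to V of respiration and of folding rose, where 1042 of 21821 genes rose in all. The ribosomal protein list took 0.903% to 1.09% of reads in the 6 inhibitor libraries and 0.492% to 0.796% in the other 9. Of 49 ribosomal protein genes 9 rose and 0 fell (19 adjusted over the list alone), with Rplp2 from 63.8 to 111 CPM (adjusted p = 0.507 with an estimated correlation). Of the oxidative phosphorylation list for complexes II to V 6 of 36 rose (10 adjusted over the list alone), with Uqcr11 and Atp5e rising by 0.74 and 0.87 on the log2 scale (adjusted p = 0.595 with an estimated correlation), and of complex I 1 of 28 rose, Ndufa2 (0 adjusted over the list alone, adjusted p = 0.735 with an estimated correlation). The complex I share was below that over all genes. On the complex I list, low-dose 1 scored -0.12, within the MPTP range of -0.15 to -0.066. Low-dose 2 and 3 scored 0.25 and 0.24. For complexes II to V, low-dose 1, 2 and 3 scored -0.062, 0.30 and 0.13, against -0.17 to -0.092 after MPTP. Of the unfolded protein list 4 of 18 rose, Xbp1 and Sdf2l1 among them (10 adjusted over the list alone), and of the heat shock list 2 of 12, Hspa1b and Hspa1a (5 adjusted over the list alone), both with adjusted p = 0.504 with an estimated correlation. Hspa1a and Hspa1b are near-identical copies, so their separate counts are uncertain. Hspa1a had 1064, 3480 and 1166 reads in low-dose libraries 1, 2 and 3, and 825, 604 and 1195 in controls 1, 2 and 3. Hspa1b had 1052, 3752 and 1241 reads in these low-dose libraries, and 691, 554 and 1086 in these controls. Low-dose 2 was thus far above the others, and control 3 lay near low-dose 1 and 3. Of the synaptic list 3 of 19 rose (4 adjusted over the list alone), with Homer1 and the postsynaptic scaffold gene Dlg4, and of the histone list 3 of 7 (4 adjusted over the list alone), with H2ac18 and H2bc4, both with adjusted p = 0.387 with an estimated correlation. The homeostatic microglia list had 0 of 20 passing, with Trem2 at 10.1 against 6.03 CPM (adjusted p = 0.242), and the inflammation list 0 of 17, with Ptgs2 at 10.2 against 1.97 CPM (adjusted p = 0.0515).

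The largest falls by the naming rule were in the homeobox gene Barhl1 (5.42 to 0.219 CPM), the glycine receptor genes Glra1 (8.13 to 0.422 CPM) and Glra4, Wnt9b, Mab21l2, Ebf3 (36.2 to 5.54 CPM), Lingo4, Col6a6 and Ubap1l (100.1 to 20.0 CPM). Without MPTP replicate 3 the log2 fold change of Barhl1 went from -4.61 to -3.21 and its call ended (adjusted p = 0.148), and without low-dose replicate 2 Barhl1 and Glra1 stood at -6.90 and -5.86. Among the largest rises were Egr2 (0.251 to 10.4 CPM), Cd4, Igfn1, Asb11, Sh3rf2 and the chemokine gene Ccl21b, which has near-identical copies beside it. In control 1, Cd4 and Sh3rf2 had 1933 and 1852 reads, against at most 899 and 806 in any inhibitor library. Egr2 and Asb11 had 500 and 213 reads in control 1, within the range of the inhibitor libraries. Igfn1 and Ccl21b were lower in every control than in every inhibitor library. Of the 51 named genes called here, 17 kept the call with each library left out in turn, among them Neurod6, Ttr, Emx1, Arc, Egr1, Abcb1a, Ebf3 and Ubap1l, and 34 lost it without at least 1 library. The number of calls fell to 421 without MPTP replicate 2, 426 without MPTP replicate 3, 884 without MPTP replicate 1, 627 without low-dose replicate 3 and 1074 without low-dose replicate 1, and was 3412 with DESeq2 and 4253 with only these groups fitted. With the regional scores as covariates it was 0, and without both libraries of high cerebellar markers it was 5288, both chosen after seeing the data.

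The high dose was compared with MPTP alone in the same way, and 236 genes rose and 193 fell. Of the endothelial and pericyte list 6 of 18 fell (15 adjusted over the list alone, adjusted p = 0.398 with an estimated correlation), with Abcb1a from 41.3 to 12.4 CPM, Flt1 from 72.8 to 20.7 CPM and the adhesion genes Cdh5 and Pecam1 by 1.70 and 1.54 on the log2 scale. Other large falls were in the smooth muscle myosin gene Myh11 (11.6 to 2.59 CPM), Xdh, Sema3g, Gbp5, Mecom and Zfp366. Neurod6 rose from 1.75 to 64.2 CPM (log2 fold change 5.19, SE 0.78, edgeR adjusted p = 0.0126), Ttr from 3.59 to 814 CPM and Arc from 20.0 to 134 CPM.

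Of the immediate early list 8 of 24 rose and 1 fell (13 and 1 adjusted over the list alone), with Junb and Egr4 rising by 2.15 and 4.13 and Klf4 falling by 1.24 on the log2 scale. Of the cortex and hippocampus list 2 of 16 rose (6 adjusted over the list alone), both lists with adjusted p = 0.398 with an estimated correlation. Of the choroid plexus list 2 of 16 rose (10 adjusted over the list alone, adjusted p = 0.432 with an estimated correlation), and of the interneuron list 1 of 12, the neuropeptide gene Npy (7.05 to 28.5 CPM; 1 adjusted over the list alone, adjusted p = 0.408 with an estimated correlation). In the striatal list 0 of 17 passed and 5 rose adjusted over the list alone, with Adora2a at 35.1 against 1.47 CPM (adjusted p = 0.0599). Of the ribosomal protein list 2 of 49 rose, Rpl13 and Rplp0 (24 adjusted over the list alone, adjusted p = 0.498 with an estimated correlation), and of the complex II to V list 5 of 36, with Cox5b and Uqcr11 (22 adjusted over the list alone, adjusted p = 0.493 with an estimated correlation). Of the histone list 2 of 7 rose, H2ac18 and H2bc4 (5 adjusted over the list alone, adjusted p = 0.155 with an estimated correlation). The other called lists, dopamine neuron, interferon, ependyma, striatal, thalamus and midbrain, unfolded protein, heat shock, complex I and synaptic, held 0 members that passed over all genes, with adjusted p from 0.498 to 0.806 with an estimated correlation. Adjusted over the list alone, 10 complex I, 3 unfolded protein and 3 synaptic members rose and 2 interferon members fell. As at the low dose, the 3 libraries had higher cortex and hippocampus scores than the 9 without inhibitor.

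In the dopamine neuron list 0 of 22 passed, with Ret at 32.0 against 83.3 CPM. Th had 21.2 ± 17.0 CPM (log2 fold change -1.30, SE 0.95, edgeR adjusted p = 0.514) and Nr4a2 18.2 ± 4.86 CPM (log2 fold change -0.09, SE 0.56). The homeostatic microglia list had 0 of 20 passing and the inflammation list 0 of 17, with 1 falling adjusted over the list alone. Of the 34 named genes called at the high dose, 4 kept the call with each library left out in turn, H2ac18 and Ccl21b among them, and 30 lost it without at least 1 library, Neurod6, Ttr, Arc and Abcb1a included. The count of calls ranged from 18 without MPTP replicate 2 to 138 without MPTP replicate 1, and was 21 without MPTP replicate 3 and 43, 22 and 92 without high-dose replicates 1, 2 and 3. It was 1742 with DESeq2, 3560 with only these groups fitted, 6 with the regional scores as covariates and 2477 without both libraries of high cerebellar markers.

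The 2 doses were compared directly. No gene differed with edgeR (0 of 21821, 486 at an unadjusted p under 0.05, 2 by DESeq2). The endothelial and pericyte list was lower at the high dose by a median of 0.17 (median -0.17, camera adjusted p = 0.00066, adjusted p = 0.785 with an estimated correlation), with Tagln at 1.04 against 3.01 CPM, Flt1 at 20.7 against 30.7 CPM and 1 of 18 members falling adjusted over the list alone. The striatal list was lower (median -0.62, Penk 221 against 367 CPM), and the dopamine neuron list was higher (median 0.66, Ret 32.0 against 18.1 CPM), both with adjusted p = 0.785 with an estimated correlation. The dopamine neuron call ended without both libraries of high cerebellar markers (adjusted p = 0.0572), and its direction turned with regional covariates (adjusted p = 0.997). The striatal list stayed called in both fits (adjusted p = 0.0025 and 0.0071). Th had 21.2 ± 17.0 against 13.2 ± 12.7 CPM, a log2 fold change of 0.68 (SE 0.94). In place of 11 called lists, 7, 5 and 6 were called without high-dose replicate 1, high-dose replicate 3 and low-dose replicate 1, and 6, 4 and 3 of these were among the 11.

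Changes of both doses against MPTP were correlated across genes at r = 0.883, with a covariance of 0.523, where genes are not independent replicates. Unchanged groups simulated against shared MPTP libraries gave a median r of 0.501 (95% of 1000 draws from -0.285 to 0.892) and a median covariance of 0.108 (up to 0.484), so the covariance was 0.414 above its simulated median. Without both libraries of high cerebellar markers the simulated values reached 0.746 for r and 0.204 for the covariance. Of the genes called, 219 rose and 170 fell at both doses, against 11.3 and 7.24 for independent lists and at most 0 in 10 simulated sets of unchanged groups. The first value leaves out the shared MPTP libraries and the second leaves out any real change, so neither gives the overlap to be had by chance here. The 3 MPTP libraries cannot be split into parts of at least 2, so part of the covariance and of the overlap may come from the shared libraries. For levodopa, r was 0.249 with the low dose and 0.214 with the high dose, with covariances of 0.113 and 0.0782. Since MPTP changed 0 genes at the adjusted threshold, none could be followed for a return towards control levels. Of 251 genes at an unadjusted p under 0.01, 208 were nearer to control after levodopa (82.9%), 232 after the low dose (92.4%) and 239 after the high dose (95.2%), against a simulated 95% range of 45.0% to 95.5%, 33.5% to 95.2% and 31.7% to 96.0% for treatments that change nothing.

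Against controls, the low dose differed in 1178 genes (598 higher, 580 lower) and the high dose in 82 (47 higher, 35 lower), by edgeR. The low-dose count was 78 without low-dose replicate 3, 248 without control replicate 2, 325 without control replicate 3, 487 and 610 without low-dose replicates 1 and 2, and 0 with the regional scores. It was 2803 with DESeq2 and 11 with only these groups fitted. The high-dose count was 17 and 19 without control replicates 2 and 3, 15, 18 and 30 without high-dose replicates 1, 2 and 3, 8 with the regional scores, 1477 with DESeq2 and 3 with only these groups fitted.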

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

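The tests of cerebellar tissue, of depth, of chromosomal clustering, of the inhibitor libraries on the cortex score and of region mix among the 50 separating genes were chosen after the results were seen. Against levodopa, the change from MPTP differed for 1814 genes at the low dose (975 higher, 839 lower) and for 542 at the high dose (271 higher, 271 lower). Each is a test of the difference itself in the edgeR fit, picked out because the libraries of these treatments differ. It does not separate treatment from dissected tissue, and levodopa 2, with high cerebellar markers, enters both.

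Control 2 and levodopa 2 stood apart from the other 13 libraries. All 16 measured cerebellum list members (100%) were higher in both than in every other library, which goes with more cerebellar tissue in these samples. Depth as the cause is argued against, since the total counts of both (2 of 2) lay inside the range of the others. The 4 splits of levodopa and control libraries that put both on 1 side called 1893, 1701, 543 and 542 genes, against 0 for the real split and the other 5, which points to a structure of the samples. A mislabelled sample stays open and untested.

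Many of the genes called in low dose against MPTP may follow a different mix of brain regions. Of 1779 called genes outside every list, 78.1% followed the cortex and hippocampus score within groups with the sign of their call. The 1-sided exact permutation p was 0.0289 over 864 permutations, whose median was 48.9%. The share passed by this 1-sided p only, as it lay just inside the central range of the permutations, with an upper bound of 78.2%. The counts with regional covariates had been seen by then, but not this share. A length or GC trend over all genes is argued against as the whole cause for the called genes as a set. Of their median size of change, 92.1% was left after subtracting it (0.87 before and 0.80 after). These genes were picked for their changes, which makes a large loss less likely. A weaker bias stays open, as changes over all genes had a Spearman rho of -0.222 with length and 0.119 with GC. The test was not run on single lists, such as the ribosomal protein list. An effect of the inhibitor cannot be told apart from a difference in dissected tissue, because all 6 inhibitor libraries lay above the other 9 on that score. Regional covariates, which share their direction with the treatment, left 0 of 1861 calls (Neurod6 went from 5.47 to 2.59 on the log2 scale). Neurod6 belongs to the cortex and hippocampus list, whose score is a covariate, so part of its loss was built into the fit. At the low dose the covariates ended the calls of the endothelial, astrocyte, dopamine neuron and interferon lists. The immediate early and synaptic calls ended too, as did the thalamus and midbrain and the cortex and hippocampus calls. Camera adjusted p ran from 0.245 to 0.982 across all of these lists. The scores of the thalamus and midbrain and the cortex and hippocampus lists are themselves covariates, so their loss was built into the fit. The ribosomal protein, complex I, complex II to V, unfolded protein, heat shock and histone lists stayed called. So did the choroid plexus and striatal lists (adjusted p = 2.4e-09 and 6.1e-05). Some lists were called only with the covariates. Among them, the oligodendrocyte list became higher, with camera adjusted p = 0.977 without the covariates and 9.7e-12 with them. The choroid plexus and striatal scores were not among the covariates, which may thus not remove every regional difference. A difference in handling may also remain. The low-dose calls that stayed, all lost with an estimated correlation (adjusted p from 0.387 to 0.735), stay open. At the high dose against MPTP and between doses, the endothelial list stayed called with these covariates (lower, camera adjusted p = 0.00043 and 0.00088).

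A set of 50 genes separated the 6 inhibitor libraries from the other 9 by at least 2-fold in every library (45 higher, 5 lower), and 20 of these lay within 1 Mb of another. Several of the 20 are near-identical copies that may be counted from the same reads, so fewer separate loci stand behind that count. Tmem254a, Tmem254b and Tmem254c, for example, had 1217, 1192 and 1208 reads in high-dose library 1. The 50 genes include Ccl21b (chromosome 4, from 42173120) and its neighbours, Tmem254a and Plac9a (chromosome 14, from 25923298 and 25888403) and the pseudogenes Pisd-ps1 and Pisd-ps2, chosen after their values were seen. A genome or copy-number difference between the mice, of which clustering is a mark, cannot be told apart from the treatment or from a separate handling of these files. Different handling of reads shared by gene copies stays open, as 1 of 478 multi-copy genes outside both clusters separated against 16 of 8976 with no shared sequence (odds ratio 1.17, 95% interval 0.028 to 7.59). Region mix stays open too, as 59.2% of their median change was left with the regional covariates and all 50 kept their direction, but genes differed: Fezf2 went from 4.27 to 0.090 and Emx1 from 5.12 to 1.76, while Tmem254a went from 1.26 to 1.36, Plac9a from 2.58 to 3.58 and Pisd-ps1 from -1.68 to -1.32. Emx1 and Neurod6, both among the 50, belong to the cortex and hippocampus list, whose score is a covariate. Part of their loss was therefore built into the fit and says nothing on region mix.

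Splits of the 6 libraries of each comparison into 3 and 3 number 10, too few for a share under 0.05. For genes, the real count and the highest other were 0 and 0 in MPTP against control (10 of 10 splits gave as many), 0 and 1 in levodopa against MPTP (10 of 10), 1861 and 0 for the low dose (1 of 10), 429 and 0 for the high dose (1 of 10), 0 and 0 between doses (10 of 10), 0 and 1893 in levodopa against control (10 of 10), 1178 and 0 for low dose against control (1 of 10) and 82 and 0 for high dose against control (1 of 10). For lists, they were 15 and 24 in MPTP against control (5 of 10), 14 and 22 in levodopa against MPTP (5 of 10), 16 and 14 for the low dose (1 of 10), 17 and 16 for the high dose (1 of 10) and 11 and 13 between doses (4 of 10).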

How the results depend on the processing

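The fits without both libraries of high cerebellar markers and with regional covariates were chosen after seeing the data, and the cause of a change was not tested unless stated. The TPM alternative was not run, as the files hold counts. RLE and upper-quartile normalization kept the total of genes called in each comparison within 1.5 times. Counts of higher and of lower genes taken apart were not held to this limit. Genes called with DESeq2 were 51 in MPTP against control, 2 in levodopa against MPTP, 3412 and 1742 for the low and high dose against MPTP, 2 between doses, 66 in levodopa against control, and 2803 and 1477 for the doses against control. Without a filter they were 1224 and 214 for the doses against MPTP and 571 and 35 against control, with more genes tested. The filter of 5 CPM gave 256 for high dose against control. Fits of only the compared groups gave 4253 and 3560 against MPTP and 11 and 3 against control. With the replicate block, high dose against MPTP gave 226 and against control 46; the numbers do not pair these libraries, and the block moved no other count by over 1.5 times. Without both libraries of high cerebellar markers the counts were 5288 and 2477 against MPTP and 1859 and 165 against control, and with regional covariates 0 and 6, and 0 and 8. Leaving out 1 library gave 0 to 1 genes in levodopa against MPTP and in levodopa against control, 421 to 1300 and 18 to 138 for the doses against MPTP, and 78 to 1444 and 15 to 65 against control. Fewer samples enter those fits.

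Called lists fell to 0 in each main comparison with an estimated correlation. Fry called 0 in MPTP against control, levodopa against MPTP and between doses, 7 for the high dose and 11 for the low dose (9 shared with camera). Without both libraries of high cerebellar markers 9 lists were called in MPTP against control and 4 in levodopa against MPTP, and regional covariates gave 7 between doses. Elsewhere the covariates kept the number of lists within 1.5 times but not the lists: 15 in MPTP against control (3 higher, 12 lower, 9 shared with the fit without them), 11 in levodopa against MPTP (11 higher, 0 lower, 5 shared), 12 for the low dose (8 shared) and 14 for the high dose (10 shared), and 2 of the shared lists had the opposite direction in each of the first 2 comparisons. With 1 library left out the lists ranged from 10 to 18, from 5 to 14 and from 5 to 13 in MPTP against control, levodopa against MPTP and between doses. The loosened set for a return to control moved from 0 to 208, 232 and 239 genes for levodopa and the low and high dose, since it holds 251 genes in place of 0.

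Of the named genes called in low dose against MPTP, all 51 lost the call with the regional covariates, and 5 of these changed sign. With the regional covariates, log2 fold changes for the low dose against MPTP became 0.37 for Mab21l2, 1.25 for Lingo4, 0.20 for Aldh1a1, 0.15 for Ret, -0.0031 for Dlg4, 0.057 for Btk, 0.74 for Th, 4.08 for Slc6a3, 0.94 for Ddc and 2.24 for Slc18a2. For the high dose they became 0.65 for Th, 3.08 for Slc6a3, 0.96 for Ddc, 1.84 for Slc18a2 and 0.27 for Ret, and between doses 0.11 for Nr4a2, -0.11 for Btk, -0.095 for Th, -1.0035 for Slc6a3 and -0.41 for Slc18a2. For levodopa against MPTP they became 1.85 for Slc6a3, 0.43 for Ddc, 1.43 for Slc18a2 and 0.10 for Mog, and in MPTP against control -0.056 for Cx3cr1. Without both libraries of high cerebellar markers, Ddc and Slc18a2 became 0.14 and 0.28 in levodopa against MPTP, and Cx3cr1 -0.076 in MPTP against control. Nr4a2 became 0.085 at the low dose with the replicate block. Leaving out 1 library moved Nr4a2 from -0.12 to 1.24 in MPTP against control, -0.74 to 0.23 in levodopa against MPTP, -0.35 to 0.49 and -0.43 to 0.41 for the doses against MPTP and -0.30 to 0.078 between doses. Cx3cr1 moved from -0.076 to 0.58 in MPTP against control, Ddc from -1.05 to 0.14 and Slc18a2 from -1.10 to 0.27 with levodopa, and between doses Btk from -0.043 to 0.24, Th from -0.21 to 1.85 and Slc6a3 from -0.64 to 5.10. Depth limits genes near the floor, such as Ccl21b, whose mean of 0.0393 CPM after MPTP lies under the 0.0516 CPM that 3 reads reach in the shallowest library.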

Other observations

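Serotonin and hypothalamic peptide genes also varied between libraries of 1 group, and were chosen after their values were seen. Tph2, the enzyme of brain serotonin synthesis, had 45.3 CPM in control 3, 109.8 CPM in levodopa 1 and 65.8 CPM in MPTP 3, and at most 8.85 CPM in the other 12 libraries. Hcrt, the orexin precursor, had 16.6 to 69.6 CPM in the MPTP libraries, 21.2 to 47.5 CPM in the high-dose libraries and at most 0.208 CPM in the controls. It had 0.0337, 22.2 and 1.38 CPM in low-dose libraries 1, 2 and 3 and 2.27, 0 and 42.3 CPM in levodopa libraries 1, 2 and 3. The glycine tRNA gene of the mitochondrial genome, TrnG, had 4.63 and 5.31 CPM at the low and high dose and 0.123 CPM after MPTP, the smallest adjusted p in both comparisons (edgeR, 5.7e-06 and 4.0e-06). It also had the smallest adjusted p of both doses against controls (edgeR, 9.7e-06 and 5.1e-06). TrnG was among the genes that separated all inhibitor libraries (4.14 to 6.94 CPM) from all others (0.044 to 0.163 CPM). Its difference cannot be told apart from a separate handling of these libraries.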
